A study of Saccharomyces cerevisiae with 7 samples.

How the data were processed

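The series compared yeast RNA from 2 stages of a bench-scale copy of the Brazilian fuel ethanol process, in 2 strains of Saccharomyces cerevisiae named CAT and PE-2. Per the labels' protocols, cells recycled from a first fermentation were held in sulfuric acid at pH 2.5 for 1.5 h. They were then fed with cane must of 18% sugars, with 50% from molasses and 50% from cane juice, at 33 °C with 10% cells. The sample before feeding was taken after the acid treatment, and the feeding sample when must addition ended at 3 h. Samples from the end of fermentation at 9 h were not analysed here. The labels describe triplicate fermentations for each strain, and 2 biological replicates of each strain were hybridised.

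Each array carried the RNA of both stages of 1 replicate, labelled with Cy3 and Cy5 from 5 µg of RNA. Of the 7 arrays, 4 had the feeding RNA in Cy5 and 3 were dye swaps of the same replicates. CAT replicate 2 had no dye swap. Every replicate lay on a slide of its own, so that slide and replicate cannot be told apart, and each strain spanned 2 slides. No slide held both strains, and the slide was used as a random block in an alternative fit of the single arrays, which also had a dye term.

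The authors deposited scanner output with mean and background intensity of each spot on a linear scale, made with Agilent Feature Extraction 9.5.3.1 per the submitters' processing notes. The deposited log10 ratio of each spot is that of red over green processed intensity, per the file headers. The deposited flags for spots well above background, saturated or outlying are a score or another code, per the file headers. Values in the deposited series matrix equalled the deposited log10 ratio multiplied by 1e+09, with the sign turned on the 3 swapped arrays, for 100% of spots within 1e-05. All 7 columns of that matrix had a median of 0, and their scale, centring and direction (feeding over before feeding) were thus known.

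Each array held 13048 spots, of which 536 were controls. The 12512 other spots were 6256 probes of 2 spots each, with 1 probe per gene, so that a choice between probes of a gene did not arise. Of the 6256 systematic names, 5756 matched the table of the R64 assembly, which was used for names and gene order alone, and 5262 genes had a standard symbol.

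Mean signals were corrected with normexp against the local background with an offset of 50 and normalized by loess within each array, with control spots at weight 0 (limma 3.58.1 in R 4.3.3). Spots flagged as outliers, 28 over the 7 arrays, were left out, and saturated spots were kept. Ratios were turned to feeding over before feeding, spots of a probe were averaged, and technical dye swaps were averaged to 1 value per replicate. Genes were kept where both spots were well above background on all arrays of a strain in at least 1 stage, which left 5391 of 6256. The 4 replicate values were fitted with lmFit and eBayes, with 1 coefficient per strain, 2 residual degrees of freedom and 4.40 prior degrees of freedom. Each strain's log2 ratio was tested against 0, as were their mean and their difference (PE-2 minus CAT), with Benjamini-Hochberg adjustment over the 5391 genes and a threshold of 0.05. Values are given as the log2 ratio ± the moderated standard error, with n = 2 replicates per strain. That error shares 1 estimate of spread over both strains, so it is equal in CAT and PE-2. It does not measure the spread of 1 strain's replicates. The number of arrays limits their precision.

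In all, 40 gene lists fixed before the data were examined were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. The estimate rests on the 2 residual degrees of freedom, which leaves that test little power. A probe that was not well above background on any array of a stage, or saturated on all of them, has only a bound. Such folds are written "at least", computed per channel after loess and Aquantile against the higher of the probe's own signal and the lowest signal among probes well above background. They are open to dye bias for CAT, whose dye swaps were not balanced. The rule for named genes, fixed with the lists, took, among genes with a symbol, the 10 largest rises and 10 largest falls of each strain among genes past the threshold with 1 sign on every array of the strain. It also took the 6 largest strain differences in each direction, up to 4 called members of each list, and a fixed set of marker genes of sugar use, stress and growth.

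The procedure was tested on simulated data before use, with 50 of 5391 genes changed in CAT at each of the log2 changes 2, 1, -1 and -2. Of those at 2 and -2, 100% were called, and of those at 1 and -1, 76% and 74%. The median estimate was 1.56 for a simulated 2, and which step drew it towards 0 was not tested. Among the unchanged genes, 4 were called in CAT, and 1 for the strain difference. The ribosome biogenesis list was shifted in CAT as well. Noise was drawn separately for each gene, both channels were about equally bright, and most genes were unchanged. The real arrays differ in these points, so the counts do not give their rate of false calls.

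The median net signal was 184 to 203 in the feeding channel of the PE-2 arrays and 69.6 to 85.1 in their channel before feeding. On the CAT arrays it was 193 to 335 and 158 to 201. Between 75.9% and 88.6% of spots were well above background in each channel. Log ratios of the dye swaps of 1 replicate correlated across genes with r = 0.975 to 0.986, the 2 CAT replicates with r = 0.933 and the 2 PE-2 replicates with r = 0.858. Genes are not independent replicates, and these r describe the arrays. Alternatives covered the background correction, offset, normalization, signal columns, series matrix, filters, dye swaps, moderation, fits of 1 strain, a replicate block and leaving out each replicate.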

Results

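Gene expression was measured on 7 two-colour arrays in cells of the yeast strains CAT and PE-2, from acid treatment to the end of must feeding. Both strains had 2 biological replicates. The question, as the series states it, was how feeding compared with the bottom of the fermentor, taken as control, in each strain. Ratios are feeding over before feeding and are relative to the typical gene of each array, since each array was centred by loess. The sample before feeding came straight from the acid treatment. Effects of the must thus cannot be told apart from those of release from acid or of time.

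In CAT, genes of protein synthesis rose with feeding and genes of respiration fell. Of 136 cytosolic ribosomal protein genes, 133 rose and 1 fell, with a median log2 ratio of 2.75. RPL42B rose by 4.31 ± 0.24 (SE, n = 2) and RPS26A by 4.22 ± 0.16. Of 39 genes of the respiratory chain and ATP synthase, 36 fell and 1 rose, with a median of -1.90, and COX5A, a cytochrome c oxidase subunit, fell by 4.19 ± 0.25. In all, 3118 of 5391 genes passed the test, 1593 higher and 1525 lower with feeding, and 1691 of them also differed by 2-fold or more. With the spike-in controls at 0, a scaling chosen after seeing the data, the median of all genes was 0.60 and the split 2775 higher and 645 lower, and with median centring in place of loess that median was 0.11.

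Both list calls were made with camera at the preset correlation (adjusted p = 2.38e-33 for the ribosomal proteins and 1.33e-11 for the respiratory chain). With an estimated correlation neither passed, at an adjusted p = 0.302 for both. That test rested on 2 residual degrees of freedom, and 0 of the 40 lists passed it in either strain or for the difference. It had little power here, so not passing it neither upholds nor refutes a call. Adjusted over the list alone, 134 ribosomal protein genes and 38 respiratory genes passed. Such counts, here and below, take rises and falls together. RPL9A and RPL9B, RPL42A and RPL42B, and other ribosomal protein pairs are near-identical copies, so values of single copies are uncertain for cross-hybridisation.

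Ribosome biogenesis genes rose in CAT with a median of 1.24, with 116 of 137 higher and 2 lower (adjusted p = 0.302 with an estimated correlation; 119 passed adjusted over the list alone). CGR1, which acts in rRNA processing, rose by 4.37 ± 0.25, and NSR1, a nucleolar protein, by 2.88 ± 0.16. Translation factors were called up (27 of 40 higher, 2 lower, median 0.71, adjusted p = 0.378 with an estimated correlation, 32 adjusted over the list alone). ANB1 rose by 3.59 ± 0.18, while DED1, an RNA helicase, fell by 2.59 ± 0.27. The RNA polymerase I and III list, which holds subunits and other factors of these polymerases, was also called up. It had 17 of 36 genes higher and 4 lower (median 0.54, adjusted p = 0.302 with an estimated correlation, 21 adjusted over the list alone). RRN11 rose by 3.39 ± 0.17. Amino acid synthesis genes were called up (39 of 66 higher, 6 lower, median 0.76, adjusted p = 0.302 with an estimated correlation, 47 adjusted over the list alone), with LEU2 at 3.95 ± 0.22 and BAT1 at 3.03 ± 0.16.

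In CAT, genes of glycolysis and ethanol formation were called up (15 of 24 higher, 3 lower, median 1.54, adjusted p = 0.378 with an estimated correlation, 19 adjusted over the list alone). PDC5, a pyruvate decarboxylase, rose by 4.33 ± 0.17 and PDC1 by 2.22 ± 0.19. PGK1 was saturated in the feeding channel and rose at least 14.6-fold, and ADH1, an alcohol dehydrogenase, at least 8.15-fold. The vacuolar proton ATPase was called up (12 of 17 higher, none lower, median 1.51, adjusted p = 0.302 with an estimated correlation, 12 adjusted over the list alone), with VMA8 at 2.29 ± 0.16. GPP1 and GPP2, glycerol phosphatases, rose by 4.04 ± 0.17 and 3.39 ± 0.19, and the osmotic response list was not called (adjusted p = 0.594, adjusted p = 0.770 with an estimated correlation).

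The gluconeogenesis and glyoxylate list, genes of growth on non-sugar carbon, was called down in CAT, with 17 of 21 members lower and 2 higher and with a median of -1.66 (adjusted p = 0.302 with an estimated correlation, 19 adjusted over the list alone). ICL1, isocitrate lyase, was at -1.81 ± 0.18 and FBP1, fructose bisphosphatase, at -2.07 ± 0.15. Of the tricarboxylic acid cycle genes, 14 of 18 fell and 1 rose, with a median of -1.48 (adjusted p = 0.302 with an estimated correlation, 15 adjusted over the list alone), and SDH2 fell by 3.72 ± 0.16. The beta-oxidation and peroxisome list had 22 of 28 members lower and 2 higher, with a median of -0.87 (adjusted p = 0.302 with an estimated correlation, 25 adjusted over the list alone). Sucrose and maltose genes had 10 of 11 members lower, with a median of -1.12 (adjusted p = 0.378 with an estimated correlation, 10 adjusted over the list alone), and SUC2, invertase, fell by 1.58 ± 0.20.

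Further lists were called down in CAT. Iron and copper genes had 25 of 32 lower and 2 higher (median -1.01, adjusted p = 0.378 with an estimated correlation, 28 adjusted over the list alone). Weak acid and low pH genes had 21 of 29 lower and 1 higher (median -1.04, adjusted p = 0.378 with an estimated correlation, 22 adjusted over the list alone). The Msn2/4 stress list had 28 of 48 lower and 3 higher (median -0.80, adjusted p = 0.378 with an estimated correlation, 34 adjusted over the list alone). Heat shock proteins had 18 of 33 lower and 2 higher (median -0.73, adjusted p = 0.378 with an estimated correlation, 20 adjusted over the list alone), and HSP104, a disaggregase, fell by 1.09 ± 0.19. Trehalose and glycogen genes had 12 of 22 lower and 3 higher (median -0.53, 0.056 with the spike-in controls at 0, adjusted p = 0.378 with an estimated correlation, 15 adjusted over the list alone). Ergosterol genes had 12 of 28 lower and 1 higher (median -0.52, 0.064 with the spike-in controls at 0, adjusted p = 0.378 with an estimated correlation, 13 adjusted over the list alone). Mitochondrial ribosomal proteins had 23 of 70 lower and 4 higher (median -0.39, 0.19 with the spike-in controls at 0, adjusted p = 0.378 with an estimated correlation, 26 adjusted over the list alone). The camera adjusted p of that list at the preset correlation was 0.0150, and 1525 of all 5391 genes were called lower. The phosphate list (13 of 23 lower, 3 higher, median -0.60, 17 adjusted over the list alone) and the aldehyde list (18 of 28 lower, 6 higher, median -0.89, 25 adjusted over the list alone) were called down too, each with an adjusted p = 0.378 with an estimated correlation. At the preset correlation their camera adjusted p was 0.0271 and 0.0177.

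DSF1, HXT17, MAN2, HXT16 and HXT15 were among the genes of largest fall in CAT. DSF1 and MAN2 encode mannitol dehydrogenases, and the HXT genes are of the hexose transporter family. DSF1 was at -6.33 ± 0.18, HXT17 at -6.20 ± 0.15 and MAN2 at -6.06 ± 0.18. HXT3, a low-affinity glucose transporter, rose by 2.51 ± 0.19, and HXT7 was not called at -0.35 ± 0.29. RGI2 fell by 5.11 ± 0.26, and TMA10, saturated before feeding, at least 22.2-fold, a lower bound with no rank against the other falls. Members of the HXT15, HXT16 and HXT17 group and the DSF1 and MAN2 pair are close copies, and their single values are uncertain. With 1 CAT replicate left out, 1350 (without replicate 1) or 1431 (without replicate 2) genes passed.

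In PE-2 too, genes of protein synthesis rose with feeding and genes of respiration fell. Of 136 cytosolic ribosomal protein genes, 131 rose and none fell, with a median of 2.09 (adjusted p = 0.313 with an estimated correlation). Adjusted over the list alone, 133 of them passed, 131 higher and 2 lower. Of 39 respiratory genes, 29 fell and 1 rose, with a median of -1.28 (adjusted p = 0.313 with an estimated correlation, 33 adjusted over the list alone). AHP1, a thiol peroxidase, rose by 4.11 ± 0.15 (SE, n = 2). In all, 2323 of 5391 genes passed the test, 1185 higher and 1138 lower, and 1177 also differed by 2-fold or more. The split was 1707 higher and 839 lower with median centring, where the median of all genes was 0.17. With the spike-in controls at 0, where that median was 0.83, it was 3547 higher and 301 lower.

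With the ribosomal proteins, 8 lists were called up in PE-2. Ribosome biogenesis genes had 75 of 137 higher and 7 lower (median 0.69, adjusted p = 0.313 with an estimated correlation, 86 adjusted over the list alone). Glycolysis and ethanol genes had 15 of 24 higher and 5 lower (median 1.91, adjusted p = 0.485 with an estimated correlation, 21 adjusted over the list alone), with PGK1 at 3.85 ± 0.21 and PDC1 at 2.49 ± 0.19. The vacuolar proton ATPase had 12 of 17 higher (median 1.46, adjusted p = 0.313 with an estimated correlation, 12 adjusted over the list alone). Amino acid synthesis genes had 29 of 66 higher and 7 lower (median 0.46, adjusted p = 0.313 with an estimated correlation, 38 adjusted over the list alone). Translation factors had 15 of 40 higher and 2 lower (median 0.36, adjusted p = 0.484 with an estimated correlation, 17 adjusted over the list alone). Cell wall genes had 18 of 35 higher and 3 lower (median 0.69, adjusted p = 0.459 with an estimated correlation, 24 adjusted over the list alone), with SLT2, a MAP kinase, at 2.22 ± 0.23. Cell cycle genes had 11 of 41 higher and 1 lower (median 0.30, adjusted p = 0.485 with an estimated correlation, 7 adjusted over the list alone), with RNR2 at 1.25 ± 0.25. The camera adjusted p of the cell cycle list at the preset correlation was 0.0271, and 1185 of all 5391 genes were called higher.

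Lists called down in PE-2 were mostly of carbon use. The sucrose and maltose list had 10 of 11 members lower (median -2.10, adjusted p = 0.313 with an estimated correlation, 10 adjusted over the list alone), with MAL31, a maltose permease, at -3.89 ± 0.26. The gluconeogenesis and glyoxylate list had 15 of 21 lower and 2 higher (median -1.20, adjusted p = 0.313 with an estimated correlation, 19 adjusted over the list alone), and JEN1, a lactate permease, fell by 3.21 ± 0.17. Tricarboxylic acid cycle genes had 12 of 18 lower and 1 higher (median -0.93, adjusted p = 0.313 with an estimated correlation, 15 adjusted over the list alone). The beta-oxidation list had 18 of 28 lower and 2 higher (median -0.75, 0.075 with the spike-in controls at 0, adjusted p = 0.313 with an estimated correlation, 22 adjusted over the list alone). Iron and copper genes had 17 of 32 lower and 1 higher (median -0.55, 0.27 with the spike-in controls at 0, adjusted p = 0.533 with an estimated correlation, 18 adjusted over the list alone). Mitochondrial ribosomal proteins had 25 of 70 lower and 2 higher (median -0.38, 0.44 with the spike-in controls at 0, adjusted p = 0.449 with an estimated correlation, 27 adjusted over the list alone). Hexose transport genes had 9 of 14 lower and 3 higher (median -0.77, 0.051 with the spike-in controls at 0, adjusted p = 0.446 with an estimated correlation, 13 adjusted over the list alone). At the preset correlation the camera adjusted p of the hexose list was 0.0266.

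The largest changes in PE-2 included many genes named for CAT. DSF1 was at -5.67 ± 0.18, RGI2 at -5.79 ± 0.26, TMA10 at -5.10 ± 0.22 and MAN2 at -5.16 ± 0.18. HXT15 and HXT16 were not well above background with feeding and were at least 16.6-fold and 16.5-fold lower. PDC5 rose by 3.65 ± 0.17, CGR1 by 3.56 ± 0.25 and HXT3 by 3.03 ± 0.19. HSP12, a small membrane-associated stress protein, rose by 3.005 ± 0.25, HSP26 by 2.03 ± 0.40, CTT1, a catalase, by 1.07 ± 0.18, and TPS1, trehalose phosphate synthase, by 1.04 ± 0.18. PMA1, the plasma membrane proton pump, rose by 1.64 ± 0.19. The Msn2/4 stress list as a whole was not called (19 of 48 higher, 9 lower, median 0.29, adjusted p = 0.149), nor were heat shock proteins (11 of 33 higher, 9 lower, median 0.34, adjusted p = 0.643).

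In CAT 19 and in PE-2 24 of the 40 lists were not called. Lists called in neither strain included sulfur and methionine (median -0.52 in CAT, adjusted p = 0.0543), nitrogen use (-0.40, adjusted p = 0.0523), oxidative stress (-0.24, adjusted p = 0.468), the proteasome (-0.27, adjusted p = 0.239) and autophagy (-0.25, adjusted p = 0.117). In PE-2 their medians were -0.18, 0.17, -0.047, -0.29 and -0.19 in the same order, with camera adjusted p from 0.181 to 0.973. Median, mean and test differed in sign in PE-2 for the trehalose, oxidative stress, nitrogen, thiamine and mating lists, and in the strain difference for the anaerobic and proteasome lists. GPD1, of glycerol synthesis, rose by 1.40 ± 0.18 in CAT and 2.57 ± 0.18 in PE-2, and ZWF1, of the pentose phosphate pathway, fell, at -1.58 ± 0.17 and -0.83 ± 0.17.

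Over both strains, 3500 genes passed the test of the mean response, 1774 higher and 1726 lower (3566 and 535 with the spike-in controls at 0). Both strains called 979 genes up and 885 down, against 350 and 322 for independent lists of the same sizes, and 29 genes were called in opposite directions. The tests of the strains share 1 estimate of spread per gene, so part of the overlap may come from that. Across 5391 genes the strain means correlated with r = 0.857 (rho = 0.825), a description over genes that are not independent replicates. Of genes called in both strains, 98.5% had the same sign. PE-2 ratios were smaller over all genes, with a slope on those of CAT of 0.702 and an SD across genes of 0.930 against 1.13. The fatty acid and phospholipid list was not called (adjusted p = 0.110 in CAT and 0.232 in PE-2), but FAS1, a fatty acid synthase subunit, was at -3.31 ± 0.17 in CAT and -2.93 ± 0.17 in PE-2, and OLE1, a fatty acid desaturase, at -3.20 ± 0.24 and -3.52 ± 0.24. THI4, of thiazole synthesis, rose by 2.34 ± 0.16 in CAT and 2.21 ± 0.16 in PE-2, while THI5, one of several near-identical copies, was at -3.27 ± 0.15 and -2.04 ± 0.15. ADH2 was at 0.00 ± 0.16 in CAT and -0.22 ± 0.16 in PE-2 and was not called.

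**Figure D1:**
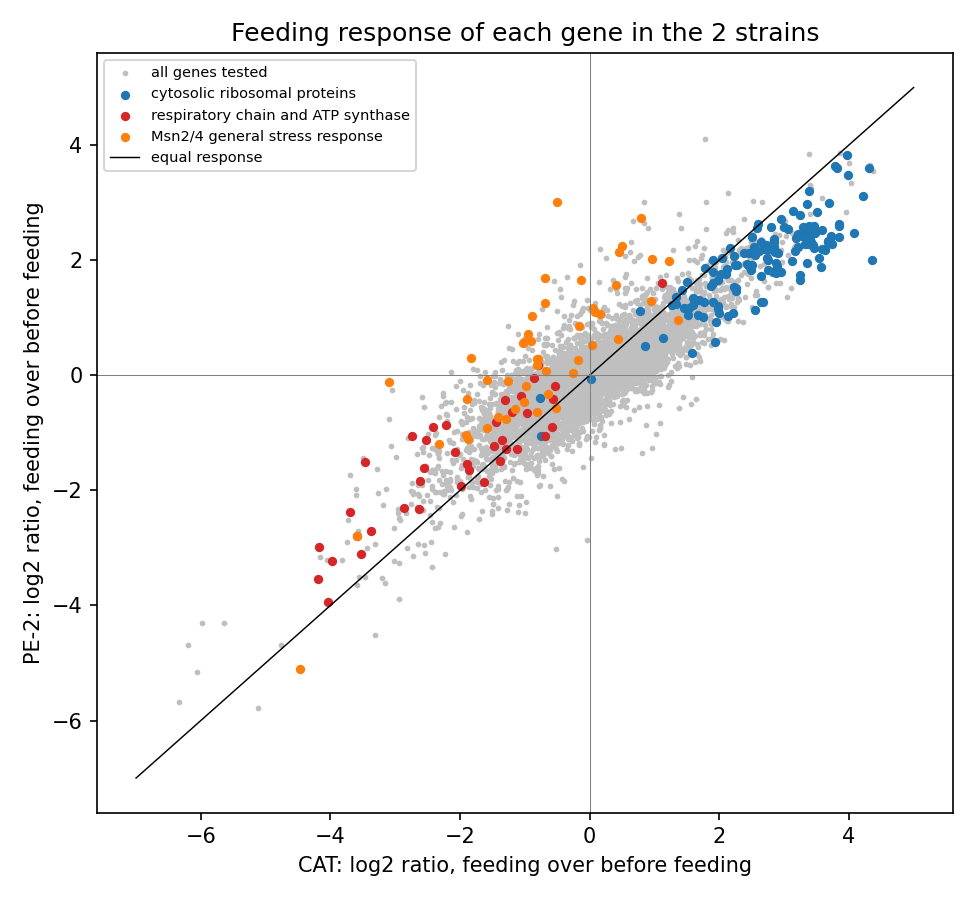
Each point is 1 of 5391 genes, with the log2 ratio of feeding over before feeding in CAT on the horizontal axis and in PE-2 on the vertical axis, and colours mark 3 gene lists. Ribosomal protein genes lie at a median of 2.75 in CAT and 2.09 in PE-2, and Msn2/4 stress genes lie at -0.80 and 0.29.

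Single stress genes had a different response in each strain. HSP12 was at -0.51 ± 0.25 in CAT and 3.005 ± 0.25 in PE-2, a difference (PE-2 minus CAT) of 3.51 ± 0.36 (adjusted p = 0.0329). DDR2, a stress-induced gene, differed by 2.98 ± 0.26, YGP1, a secreted glycoprotein, by 2.38 ± 0.31, and SED1, a cell wall protein, by 2.37 ± 0.22. RPS0A and RPL16A, ribosomal proteins, were lower in the PE-2 response, at -1.68 ± 0.23 and -1.60 ± 0.22. In all, 49 genes passed, 41 higher and 8 lower in PE-2, and each had an estimated difference of 2-fold or more. With median centring 108 were higher and 5 lower. The 49 included HXT16, which was not well above background in PE-2 with feeding, so the size of its difference is not measured. That difference turned to -0.28 with the deposited log ratio. No list of genes was called for the difference with an estimated correlation (lowest adjusted p = 0.367 with an estimated correlation).

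The Msn2/4 stress list had a median difference of 1.01, with 7 of 48 members called higher in PE-2 and none lower, and 27 adjusted over the list alone (camera adjusted p = 1.27e-15, adjusted p = 0.367 with an estimated correlation). Heat shock proteins had a median difference of 1.13, with 4 of 33 called higher and 18 adjusted over the list alone (adjusted p = 0.367 with an estimated correlation). Cytosolic ribosomal proteins had a median difference of -0.69, with 2 of 136 called lower in PE-2 and 50 adjusted over the list alone (adjusted p = 0.367 with an estimated correlation). PE-2 was also set against the CAT ratio times the slope of 0.702, a comparison chosen after seeing the data. The median difference was then 0.12 for the ribosomal proteins, 0.85 for the Msn2/4 list and 0.68 for heat shock proteins. Noise in the CAT ratios draws a least-squares slope towards 0, by an amount not measured here. The change of sign of the ribosomal proteins may therefore come from the slope. The oxidative stress list was not called for the difference (adjusted p = 0.0817). PMA1 differed by 2.19 ± 0.26 (adjusted p = 0.0392), from -0.55 ± 0.19 in CAT, a value of 0.034 with the spike-in controls at 0, to 1.64 ± 0.19 in PE-2.

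Without CAT replicate 1 or 2 limma called 0 genes (688 and 525 at an unadjusted p under 0.05), without PE-2 replicate 1 it called 12 and without PE-2 replicate 2 it called 115. With no filter on dim probes it called 0 (1460 unadjusted), and with the replicate number as a block 0 (738 unadjusted). With the replicate numbers crossed between strains in that block, a choice made after seeing the data, it called 1812, of which 855 were higher and 957 lower in PE-2. ZNF1, at -2.86 ± 0.15 in PE-2, was not well above background at either stage in CAT, so its difference of -2.82 ± 0.21 has no measured CAT response.

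**Figure D2:**
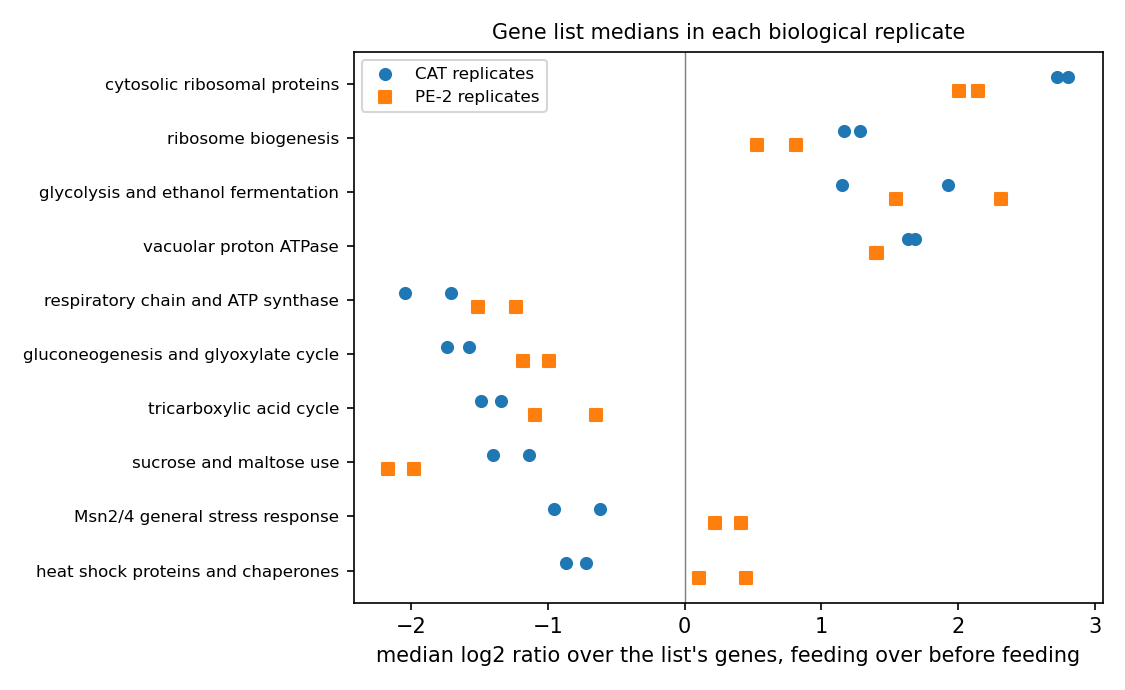
Points are the median log2 ratio over the genes of each of 10 lists in each biological replicate, with circles for the 2 CAT replicates and squares for the 2 PE-2 replicates. The Msn2/4 stress list lies at -0.62 and -0.95 in CAT and at 0.22 and 0.41 in PE-2.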

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

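All tests of explanations in this part were chosen only after the result was seen. The strains' responses differed by the test of the difference itself in 49 genes. Values are PE-2 minus CAT log2 ratios. HSP12 differed by 3.51, DDR2 by 2.98, YGP1 by 2.38, SED1 by 2.37, AHP1, a thiol peroxidase, by 2.33 and HXT5, a hexose transporter, by 2.32, all higher in PE-2. ZNF1 differed by -2.82, MOR1 by -2.21, RPS0A by -1.68 and RPL16A by -1.60. ZNF1 was not well above background in CAT.

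Camera called 15 lists for the difference at the preset correlation and 0 with an estimated correlation (1 at an unadjusted p under 0.05; lowest adjusted p = 0.367 with an estimated correlation). Median differences of lists higher in PE-2 were 1.13 for heat shock proteins, 1.01 for the Msn2/4 stress list, 0.76 for histones, 0.57 for weak acid and low pH genes and 0.56 for the respiratory chain. They were 0.55 for trehalose and glycogen, 0.44 for the cell wall, 0.41 for nitrogen use, 0.38 for iron and copper, 0.37 for ergosterol and 0.29 for the tricarboxylic acid cycle. Lists lower in PE-2 had medians of -0.69 (cytosolic ribosomal proteins), -0.58 (sucrose and maltose), -0.56 (ribosome biogenesis) and -0.32 (RNA polymerases I and III). Against the CAT ratio times the slope over all genes of 0.702, medians were 0.12 for cytosolic ribosomal proteins, -0.15 for ribosome biogenesis, -0.11 for the polymerases, -0.058 for the respiratory chain and -0.077 for the tricarboxylic acid cycle. Compression by the dimmer PE-2 channel is not excluded for these 5 lists. No bound was set for this comparison, and noise in the CAT ratios lowers the slope. It therefore does not exclude compression for the other lists either. The same medians were 0.85 for the Msn2/4 list, 0.73 for histones, 0.68 for heat shock proteins, 0.49 for trehalose and glycogen, 0.47 for the cell wall and 0.31 for weak acid and low pH genes. They were 0.27 for nitrogen use, 0.18 for iron and copper, 0.13 for ergosterol and -1.03 for sucrose and maltose, which lay further from 0 than without the slope.

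The Msn2/4 stress list had a higher median in the PE-2 response than in that of CAT, with 7 of 48 members called for the difference (adjusted p = 0.367 with an estimated correlation), as did heat shock proteins, with 4 of 33 called (adjusted p = 0.367 with an estimated correlation). The channel before feeding was dimmer in PE-2, which would draw ratios towards 0, but the median of the Msn2/4 list was 0.29 in PE-2, above 0, where compression alone keeps the sign of CAT. A single deviating replicate is argued against by the 4 medians of a PE-2 replicate minus a CAT replicate, the lowest of which was 0.90. Differences between slides stay open and cannot be told apart from strain, since each slide held 1 replicate and the exact two-sided permutation p of 0.333 is the smallest that 4 replicates can give. A difference between the strains is the biological explanation left open, and it was not tested apart from slides.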

How the results depend on the processing

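The crossed replicate block and the spike-in scaling were chosen only after seeing the data; the other alternatives were planned. Counts that stayed within 1.5 times are not repeated. Requiring a 2-fold change gave 1691 genes in CAT, 1177 in PE-2 and 1339 over both strains, by construction fewer. Leaving out 1 replicate gave 1350 to 3330 genes in CAT (1350 without CAT replicate 1, 1431 without CAT replicate 2), 1636 to 1806 in PE-2, 2433 to 3300 over both and 0 to 115 for the strain difference, with the lone replicate assumed to vary like the other strain's. List counts then ran from 21 to 22 in CAT, 16 to 17 in PE-2 and 15 to 18 for the difference.

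Against 49 genes, the strain difference had 79 without background correction, 169 with an offset of 10, 113 with median centring, 104 with the deposited log ratio or the series matrix and 136 with processed signals. It had 323 in the fit of single arrays with both a dye term and slide as a random block, and 13 on arrays with feeding in Cy5. It had 30 with trend and robust moderation, 197 with the spike-in scaling and 0 without the filter on dim probes (1460 at an unadjusted p under 0.05). The cause was not tested. With an estimated correlation camera called 0 lists in CAT, 0 in PE-2 and 0 for the difference (6, 5 and 1 unadjusted).

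The labels give no pairing of replicates across strains. Deviations of same-numbered replicates correlated with r = -0.573 across genes, which with 2 replicates is the same size with a plus sign for crossed ones, and CAT replicate 1 correlated with PE-2 replicate 2 at 0.872 against 0.794 with PE-2 replicate 1. An axis was thus shared across strains by CAT replicate 1 and PE-2 replicate 2 against the other pair, and its cause was not tested. With the replicate block limma called 2442 genes in CAT, 1555 in PE-2 and 0 for the difference (738 unadjusted), and with a block of those crossed pairs 3963, 3331 and 1812, the last with 855 higher and 957 lower in PE-2. With the spike-in scaling, which by construction adds 1 shift per replicate, PE-2 had 3848 genes.

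That scaling turned the sign, by its construction, of PMA1 (0.034), FLO1 (0.046), FLO5 (0.11), GAL4 (0.062), FUS2 (0.011) and STE6 (0.019) in CAT, and of HXT5 (0.052), FLO5 (0.24), FUS2 (0.27) and SUL1 (0.26) in PE-2. It did so for the medians of trehalose and glycogen (0.056), mitochondrial ribosomal proteins (0.19) and ergosterol genes (0.064) in CAT. In PE-2 it did so for hexose transport (0.051), beta-oxidation (0.075), mitochondrial ribosomal proteins (0.44) and iron and copper genes (0.27). The strain difference of HXT16 turned to -0.28 with the deposited log ratio, -0.25 with processed signals and -0.28 with the series matrix, and HXT16 was not well above background in PE-2 with feeding. The brightest probe per gene was not run, since each gene had 1 probe.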

Other observations

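Of the tests in this part, those of the dye effect and of uneven spike-in addition were chosen only after the result was seen. Outside the comparisons above, PUT1, proline oxidase, fell, at -4.17 ± 0.19 (SE, n = 2) in CAT and -3.15 ± 0.19 in PE-2, as did GDH2, a glutamate dehydrogenase, at -2.32 ± 0.16 and -2.31 ± 0.16. ATG39, a receptor of nuclear autophagy, fell too, at -3.46 ± 0.26 and -3.50 ± 0.26. IZH1 and IZH2, of the zinc list, were at -3.19 ± 0.19 and -2.45 ± 0.21 in CAT and at -2.25 ± 0.19 and -2.90 ± 0.21 in PE-2. The nitrogen, autophagy and zinc lists were not called in either strain.

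Probes of 6 genes were well above background on all arrays of CAT at both stages and on none of PE-2, and those of 2 genes the other way round, a rule chosen after the values were seen. ZNF1, not well above background in CAT, fell short of this rule in PE-2. The probe signal of YMR326C was at least 25.8-fold higher in CAT, that of AAD14 at least 4.22-fold and that of TFA1 at least 2.37-fold. That of AQY3 was at least 1.55-fold higher in PE-2. These signals lie across slides and cannot be told apart from slide. Whether the probes match the genes of both strains was not tested.

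Gene signal over the spike-in controls stood higher in the feeding channel, by 0.71, 0.46, 0.74 and 0.90 on the log2 scale in the 4 replicates (10 probes each). The 0.46 of CAT replicate 2, which had 1 dye orientation, took the ratio of the spike-in mixes from the 3 swapped pairs and is not independent of them, in the means and the sign test too. A dye effect is argued against by the swapped pairs, whose lowest shift was 0.71. Single orientations varied, with 1.02 and, in the dye swap, 0.45 for PE-2 replicate 1, and 0.65 and 1.16 for PE-2 replicate 2. The value of CAT replicate 2, from 1 orientation, is thus imprecise. The loess curve stays open: with median centring the mean shift was 0.42 ± 0.18 (SD, n = 4) against 0.70 ± 0.18 after loess, above the stated bound by less than its spread, a margin set after the value was seen. Uneven addition of the spike-in mixes also stays open, since the exact two-sided sign test p of 0.125 is the smallest that 4 replicates can give. A higher amount of messenger RNA with feeding may be a further explanation, and it was not tested.

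The falls of HXT15, HXT16, HXT17, MAN2 and DSF1 were among the largest of CAT. Probes shared between near-identical genes stay open for all 5. The 60-base probes of HXT15 and HXT16 had 24 bases in a row in common and those of other pairs 5 to 7, but probes were compared only with each other, not with the transcripts of the other copies. Position near chromosome ends also stays open: the 251 genes nearest the ends had a median of -0.53 over both strains and the 5140 other genes 0.04, between the bounds set for that test. No biological explanation was tested.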
